A study of Drosophila simulans with 12 samples.

How the data were processed

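Gene expression was measured in testis and in abdomen of Drosophila simulans males of 2 lines, each carrying a segment of the X chromosome from D. mauritiana. Males of one line were sterile and males of the other fertile. Per the labels, 3 RNA extractions were made and hybridised for each line and tissue, which gave 12 arrays in 4 groups of 3. The males were 3 to 4 days old, with on average 150 males dissected for testis and 50 for abdomen. Nothing in the labels says that the 3 extractions came from separate cultures, so p-values measure the spread between these arrays, which may be technical. The arrays were of 2 Affymetrix designs, one per tissue, both made for D. melanogaster genes. A probe set summarises several short probes of 1 transcript. Mismatches between these probes and the D. simulans sequence were not corrected.

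The deposited values are intensities on a linear scale. For abdomen they are MAS5 signals, per the submitters' processing notes, all above 0. The same notes name MAS5 for testis, but the deposited testis intensities fall below 0 in 26 to 37 probe sets per array, which MAS5 signals cannot do. The way the testis intensities were made is therefore not given in the sources used here. Array medians lay between 212 and 222 in testis and between 208 and 223 in abdomen, so both tables were used on the scale deposited. In testis, however, the medians of the sterile arrays (212 to 216) all lay below those of the fertile arrays (219 to 222). The standard errors leave out this offset, so small testis changes depend on scaling. The authors' deposited table of fertile against sterile testis gives, per the file headers, the percent of each line's arrays with a present call, a fold score, its lower bound, a p-value, a paired p-value and a mark on selected probe sets. The authors' detection calls as a percent were used for the filter. The authors' signed fold score and the deposited p-value columns were used only to describe that table. Its mean intensity column lay within 2 percent, or 2 intensity units, of the fertile testis mean for 99.7% of probe sets. Its 12 columns of values and calls per array were not used, because their names match both a testis and an abdomen sample.

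Intensities below 0 were set to 0, which the design fixed before the data were examined had not foreseen, and log2(intensity + 16) was taken. Fold changes are on that scale, which understates changes of dim genes, and are sterile over fertile. Testis probe sets were tested if called present on all 3 arrays of at least 1 line, which kept 9927 of 18769. Abdomen calls were not used here, so abdomen probe sets were tested if their mean log2 value reached the median of the 13966 non-control probe sets, which kept 6983. The 44 control probe sets of the abdomen design stayed out. Gene symbols came from the platform annotation. In testis 13647 probe sets had 1 symbol, 402 several and 4720 none. In abdomen 12443 had 1 symbol, 327 several and 1196 none. None of 11982 symbols of the testis design matched the symbols of the D. simulans gene table, so no symbol was updated and no chromosome was assigned. A gene was represented by its probe set with the highest mean.

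Each tissue was fitted separately with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with an intensity trend, and a Benjamini-Hochberg adjusted p under 0.05 was called. The difference between tissues was the log2 fold change of sterile over fertile in testis minus that in abdomen, fitted on genes tested in both. There were 24 gene lists fixed before the data were examined, and those with at least 5 tested genes entered limma's camera test with a preset correlation of 0.01, set beside camera with an estimated correlation and fry. Fry asks whether a list's genes move one way on balance and does not compare them with other genes. Where a testis probe set was called absent on all 3 sterile arrays, its fall is given as a fold against the lowest present value. That fold is the fertile mean against the sterile mean, on the log2(intensity + 16) scale with values below 0 set to 0. The sterile value on each array was the higher of its own and the lowest among probe sets present on all 3 sterile arrays. That lowest present value was 8.85 to 18.4 on the sterile arrays but -33.4 to -13.1 on the fertile ones. On the fertile arrays it sets no limit, so no fold is given for rises of probe sets absent on all of them. The lowest present value is no detection limit, since probe sets were called absent at higher intensities, such as OdsH at 127.6 in sterile testis. These folds are therefore no strict lower bounds. The fitted differences between tissues of genes absent in 1 testis line depend on the pseudocount and are no measured sizes. Single values were compared with exact two-sided permutation tests, whose smallest p for 3 against 3 arrays is 0.1. The number of arrays limits the precision. Fisher's exact test was used for genes shared between tissues.

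The genes named were set by a rule fixed before the data were examined. OdsH was always named. In each tissue the rule then took the 10 largest rises and the 10 largest falls among called probe sets with 1 symbol and no overlap between the lines, and up to 4 called members per list. Of a list with no called member it allowed at most the member with the smallest p, and no such member was taken. It took the 5 largest differences between tissues in each direction. A gene outside this rule is said to be chosen after its values were seen, apart from unc-4, which shares a fixed list with OdsH.

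The scripts were tested on simulated data. For the testis comparison, with 9927 probe sets, 97% of simulated changes of 0.5 and 100% of changes of 1 on the log2 scale were recovered, and 0.072% of unchanged probe sets were called. For the abdomen comparison, with 6983 probe sets, 0% of changes of 0.5 and 8% of changes of 1 were recovered, and 0.0147% of unchanged probe sets were called. For the difference between tissues, with 4774 genes, 57% of changes of 1 in testis alone were recovered and 0.612% of unchanged genes were called. For the gene lists, with 8050 genes in testis and 5891 in abdomen, camera called 30 simulated genes shifted by 0.3 in both tissues and 30 genes not shifted in neither. Genes were simulated without correlation between them, so this does not check the preset correlation. In the testis simulation 9727 of 9927 probe sets were unchanged, and no offset between the lines was added. Its rate of false calls therefore does not carry over to the testis arrays, whose medians differ between the lines.

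The letters A, B and C are shared by both lines. In abdomen, arrays with the same letter deviated from their group means together, with correlations across probe sets of 0.15, 0.288 and 0.26. All 3 exceeded 0.1, the limit set for treating the letters as pairs, so a fit with the letter as a block is given beside abdomen results it changes. The pairing comes from this check and not from the labels. Alternatives covered the filter, quantile normalization, median centring, pseudocounts of 1 and 64, the replicate block, the variance model, the threshold, the set test and leaving out each array. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.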

Results

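Expression profiles were obtained from testis and abdomen of sterile and fertile introgression males, with 3 arrays per line and tissue. Both lines carry D. mauritiana DNA on the X chromosome and, as the series design states it, differ in a stretch of about 3 Kb that holds exons 3 to 4 of OdsH, a homeobox gene known as a hybrid sterility gene. The comparisons ask which transcripts differ between sterile and fertile males in each tissue, and whether that difference varies between the tissues. A single sterile line was compared with a single fertile line, so differences cannot be credited to the introgressed stretch alone. In testis, arrays of the same line correlated across probe sets at 0.997 to 0.998 and arrays of different lines at 0.964 to 0.965. In abdomen the ranges were 0.905 to 0.937 within lines and 0.89 to 0.932 between lines. Genes are not independent replicates in these correlations. The median residual SD on the log2 scale was 0.05 in testis and 0.30 in abdomen.

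Testis signals of the sterile line differed from those of the fertile line mostly by small amounts, with a few probe sets near detection in one line and bright in the other. Of 9927 probe sets tested, 5995 passed, 2245 higher and 3750 lower in the sterile line, and the median absolute log2 fold change among them was 0.24. A change of at least 1 on the log2 scale was reached by 227 of these, 95 higher and 132 lower, and a change of at least 3 by 40. The 3 sterile values did not overlap the 3 fertile ones in 64.3% of probe sets, where chance gives 10%. The balance of directions depended on scaling. With arrays centred on their medians 2941 were higher and 2941 lower, and after quantile normalization 3028 were higher and 2959 lower, while the median log2 fold change of all probe sets moved from -0.04 to 0.01 under both. By detection call, 89 probe sets were present on all 3 sterile and on none of the fertile arrays, and 127 showed the opposite pattern.

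The largest rise in sterile testis was that of Acp53C14b, an accessory gland protein gene, at an intensity of 7077 ± 134 (SD, n = 3) against -33.1 ± 0.447 (adjusted p = 7.24e-24). Its 3 fertile values were set to 0 before the test, so this p measures no spread among the fertile arrays. alphaKap4, of the importin alpha family, measured 1962 ± 65.3 in sterile against -53.1 ± 9.23 in fertile testis, and the serpin gene Spn28Da 990.9 ± 47.2 against -1.48 ± 3.46. CG15253 (384.4 ± 10.2 against -21.8 ± 6.49), nau, a myogenic transcription factor gene (307.9 ± 6.24 against 10.7 ± 0.236), Nazo (303.7 ± 8.1 against 11.4 ± 6.09) and Obp56h, an odorant-binding protein gene (456 ± 35.7 against 24.6 ± 0.785), also rose. All 7 were called absent on the 3 fertile arrays, and the size of their fitted folds depends on the pseudocount, so none is given. Abdomen log2 means, sterile and fertile, were 10.9 and 10.4 for Acp53C14b and 8.25 and 8.58 for Nazo. Whether these testis signals reflect transcript levels or a sequence variant under the probes of 1 line stays open. Cyp28d2, a cytochrome P450 gene, rose by 2.59 ± 0.05 (SE) on the log2 scale, from 99.7 ± 4.99 to 680.6 ± 11.4. CG15394 rose from 450.3 ± 9.16 to 2538 ± 16.4 (SD, n = 3), and CG12917 from 283.5 ± 4.08 to 1358 ± 1.72.

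Among the largest falls in sterile testis, CG18179 was 52-fold lower against the lowest present value. It measured -9.48 ± 5 (SD, n = 3) against 1484 ± 29.2 (adjusted p = 7.8e-20). Its 3 sterile values were set to 0 before the test, so this p measures no spread among the sterile arrays. Eaat2, a transporter of excitatory amino acids, was 32.6-fold lower against the lowest present value and CG8997 32-fold. CG17197 was 28.9-fold, CG17290 18.6-fold and CG12057 13.4-fold lower on the same measure. All of these were called absent on the 3 sterile arrays. CG15631 fell from 2184 ± 40.6 to 6.75 ± 4.6 and was called present on 33% of sterile arrays. One probe set of CG9945 fell from 673.1 ± 28.5 to 8.86 ± 4.85, while a probe set of CG9945 with a higher mean rose by 0.41 ± 0.04 (SE) on the log2 scale. kl-3, a Y-linked gene for an axonemal dynein heavy chain, fell from 394.1 ± 17 to 5.68 ± 9.12 (adjusted p = 5.42e-12) and was called present on 33% of sterile arrays. For CG15631, CG9945 and kl-3 the size of the fitted fold depends on the pseudocount, so none is given. Jon25Bi, a Jonah-family digestive protease gene, was 27.2-fold lower against the lowest present value.

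**Figure D1:**
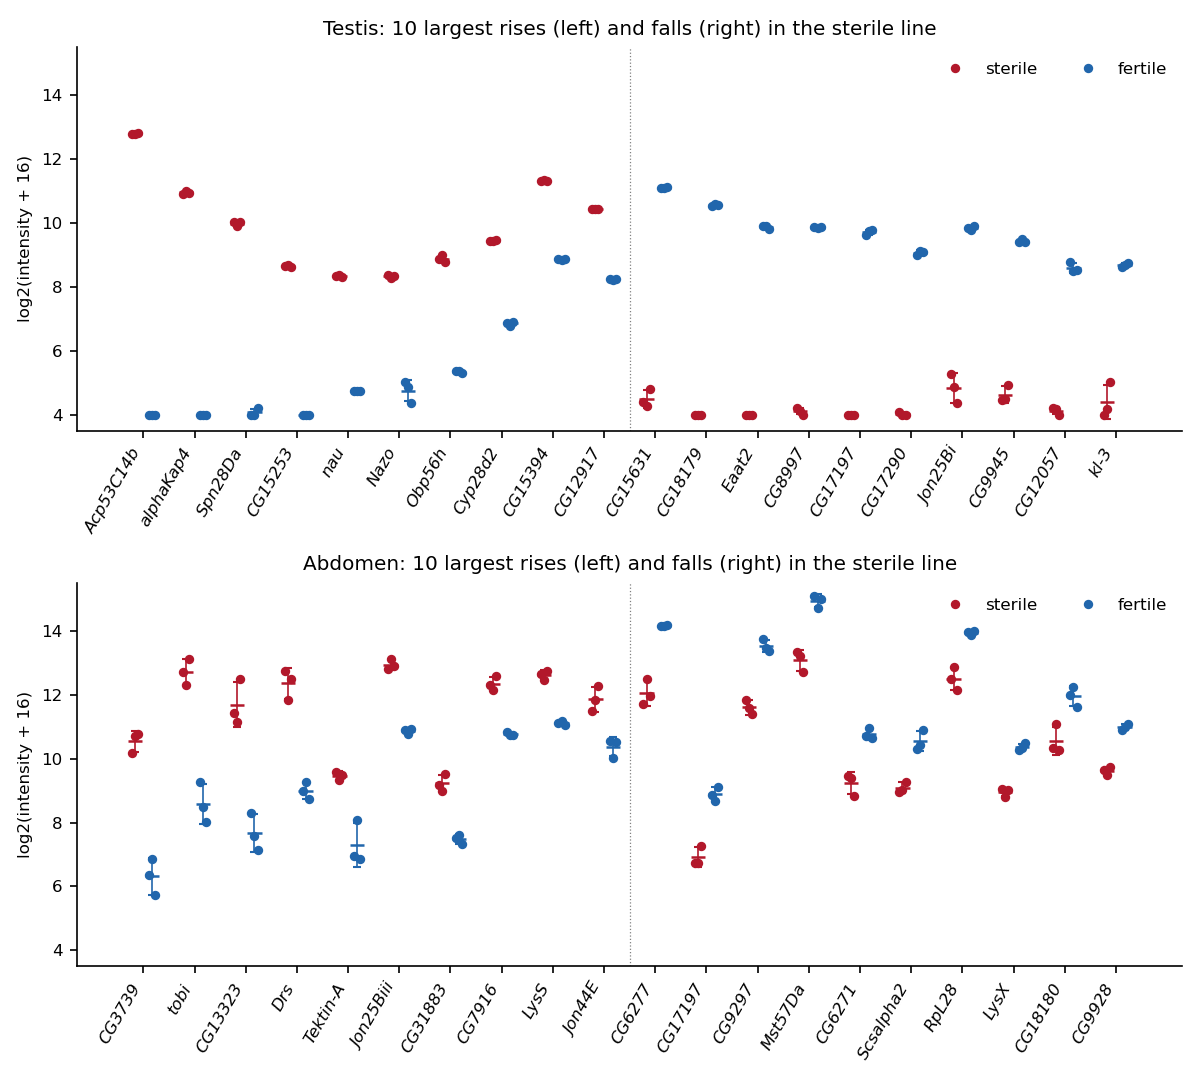
Log2(intensity + 16) on each array (points), with the mean (line) and SD (bar) of 3 arrays per line, for the 10 largest rises and the 10 largest falls in sterile testis (top) and sterile abdomen (bottom). The fertile testis values of Acp53C14b lie at the floor, where an intensity of 0 or less is plotted, and the sterile ones average 7077 in intensity.

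Genes of digestive enzymes of the midgut were lower in sterile testis samples as a group. Of 19 tested, 18 fell and none rose, with a median log2 fold change of -2.79. The median stayed at -2.79 with the 6 members absent in the sterile line taken at no less than the lowest present value. The filter kept 19 of 38 list genes on the array, and 8 of the 19 were detected on all sterile arrays. The others passed the filter only through the fertile line, where they were higher, so the count, the median and the list test may overstate the fall. Among the 8, log2 fold changes ran from -4.08 to -0.13. The log2 fold changes were -4.08 ± 0.06 (SE) for yip7, -4.04 ± 0.05 for Jon65Aiii, -3.54 ± 0.05 for Bace and -3.48 ± 0.03 for Jon65Aiv. Jon65Aiv measured 290.6 ± 5.95 in sterile and 3393 ± 18.3 in fertile testis (SD, n = 3). The list passed camera (adjusted p = 1.66e-11 over 22 lists), the only list to do so, but not with an estimated correlation (adjusted p = 0.216). Its mean level per array was 6.61 ± 0.08 on the log2 scale in sterile and 9.05 ± 0.01 in fertile testis (exact permutation p = 0.1, the smallest possible). Midgut enzymes mark another tissue than testis. Of the markers of other tissues, fat body genes counted 4 lower and 1 higher of 7 (median -0.13, camera adjusted p = 0.309), with log2 fold changes of -0.40 for both Cyp4g1 and apolpp. Fat body genes counted 3 lower and 2 higher after quantile normalization (median -0.06), and 4 lower and 1 higher after median centring (median -0.09). Muscle genes counted 6 lower and 2 higher of 17 (median -0.04, camera adjusted p = 0.963), with -0.42 for Zasp52 and 0.26 for Act88F. Muscle genes counted 5 higher and 5 lower after median centring (median 0.01) and 6 higher and 3 lower after quantile normalization (median 0.04).

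Accessory gland and ejaculatory duct genes were abundant in the testis samples of both lines, at a mean of 11.61 ± 0.01 (SD, n = 3) on the log2 scale in sterile and 11.44 ± 0.01 in fertile samples. Of 27, 14 fell and 3 rose, and 11 fell and 5 rose after median centring (median -0.04). The log2 fold changes were -0.60 ± 0.02 (SE) for aqrs, -0.56 ± 0.03 for Acp29AB and -0.38 ± 0.02 for Sems. On the deposited scale the median was -0.08 while the mean was 0.17, because of Acp53C14b, and camera pointed down (adjusted p = 0.129).

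Genes of spermatogenesis changed little and in both directions. Structural genes of spermiogenesis counted 8 higher and 2 lower of 17 (median 0.03, camera adjusted p = 0.309), with log2 fold changes of 0.31 ± 0.05 (SE) for Mst89B and -0.51 ± 0.03 for djl. After median centring they counted 10 higher and 1 lower (median 0.08). Of 14 cup and comet genes, which are transcribed after meiosis, 7 rose and 2 fell (median 0.05, adjusted p = 0.0927), and d-cup rose by 0.32 ± 0.03. With median centring 10 of these rose and 1 fell (median 0.10, camera adjusted p = 0.0506). The testis-specific proteasome genes counted 7 higher and 2 lower of 11 (median 0.14, adjusted p = 0.0613), with Prosbeta5R2 at 1088 ± 52 in sterile and 682.5 ± 11.2 in fertile testis (SD, n = 3). This list passed after median centring (adjusted p = 0.0366) and quantile normalization (adjusted p = 0.0457), with 9 higher and 1 lower under both. Its adjusted p with an estimated correlation was 0.386. Among meiotic arrest genes, which control transcription in spermatocytes, 4 of 12 rose and 2 fell (median 0.10, adjusted p = 0.256). mip40 rose by 0.48 ± 0.03 and aly fell by 0.18 ± 0.04. Meiosis genes counted 2 higher and 3 lower of 12 (median -0.01, adjusted p = 0.967, with the direction turning up under both scaling alternatives), with -0.41 ± 0.06 for tef. Germline stem cell and spermatogonia genes counted 2 higher and 3 lower of 9 (median -0.10, adjusted p = 0.963), with log2 fold changes of -0.81 for hts, which encodes an adducin, and -0.59 for Rbp9. A dim probe set of hts rose by 0.48, against 4 that fell. The piRNA pathway, which silences transposons, had 3 higher and 1 lower of 11 (median 0.08, adjusted p = 0.383). cuff rose by 0.72 ± 0.09 and aub fell by 0.50 ± 0.06.

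Axoneme and sperm motility genes counted 5 higher and 4 lower of 15 (camera adjusted p = 0.509), with a median of 0.03, a mean of -0.29 set by kl-3, and camera pointing up. Dhc62B rose by 0.42 ± 0.04 (SE). Y-linked genes went both ways, with 3 of 6 higher and 2 lower (median -0.01, 0.03 after median centring, adjusted p = 0.963). kl-5 fell by 0.97 ± 0.07 beside kl-3, while kl-2 rose by 0.24 ± 0.06 and Pp1-Y2 by 0.13 ± 0.03. Genes of spermatid individualization, the step that separates sperm from a syncytium, counted 1 higher and 8 lower of 16 (median -0.07, adjusted p = 0.398), 2 higher and 6 lower after quantile normalization, and 2 higher and 5 lower after median centring (median -0.02). klhl10 rose by 0.33 ± 0.02, and its partner in the testis ubiquitin ligase, Cul3, fell by 0.20 ± 0.02. Of the 4 sperm leucyl aminopeptidases, too few for a list test, 2 rose, S-Lap5 by 0.27 ± 0.03 and S-Lap7 by 0.06 ± 0.02, and none fell. S-Lap7 did not pass without fertile replicate A or without the variance trend. Genes of somatic cyst, hub and sheath cells counted 5 higher and 4 lower of 15 (median 0.02, adjusted p = 0.416), with a log2 fold change of -0.27 ± 0.03 for Stat92E. The JAK/STAT ligand gene upd1 rose from 32.1 ± 7.85 to 96.2 ± 1.81 (SD, n = 3). It was called present on 33% of fertile arrays, and its fitted fold depends on the pseudocount, so none is given.

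Detoxification genes counted 18 higher and 50 lower of 89 in sterile testis (median -0.18, camera adjusted p = 0.0927). The log2 fold changes were -1.14 ± 0.05 (SE) for Cyp6a23, -0.95 ± 0.03 for Cyp6d5 and -0.93 ± 0.04 for Cyp6a21. This list passed after median centring (adjusted p = 0.0366) and quantile normalization (adjusted p = 0.0425), and its adjusted p with an estimated correlation was 0.386. Cytoplasmic ribosomal protein genes counted 1 higher and 20 lower of 32 with a median of -0.06 (adjusted p = 0.0927), 2 higher and 18 lower after quantile normalization, but 3 higher and 7 lower after median centring. RpL34a fell by 0.22 ± 0.02. Antimicrobial and immune peptide genes counted 4 higher and 2 lower of 11 (median 0.08, adjusted p = 0.129). Drs, which encodes the antifungal peptide drosomycin, rose from 534.2 ± 4.58 to 2464 ± 81.2 (SD, n = 3) and Tep4 rose by 0.82. Odorant-binding protein genes counted 7 higher and 7 lower of 20 (median 0.02, adjusted p = 0.416), Obp99b rising by 0.91 ± 0.07. Of 5 heat shock genes, 1 rose and 2 fell (median 0.03, mean -0.15, camera down with adjusted p = 0.963), but 3 rose and 2 fell under both scaling alternatives, and Hsp27 fell by 0.58 ± 0.03. Heterochromatin protein genes counted 2 higher and 7 lower of 14 (median -0.11, adjusted p = 0.792), with HP1c at 967.2 ± 35.9 in sterile and 413.2 ± 23.2 in fertile testis (SD, n = 3) and a log2 fold change of -0.38 for cal1. Of 6 dosage compensation genes none rose (1 after quantile normalization) and 2 fell, with -0.27 ± 0.04 (SE) for Clamp and -0.32 ± 0.09 for JIL-1 (median -0.10, adjusted p = 0.792). No list passed camera with an estimated correlation, and 16 of the 22 passed fry. Counts adjusted over the list alone were the same except for midgut enzymes (19 lower), meiotic arrest (4 higher, 1 lower), meiosis (1 higher, 3 lower), germline stem cells (2 higher, 2 lower) and fat body (1 higher, 5 lower).

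**Figure D2:**
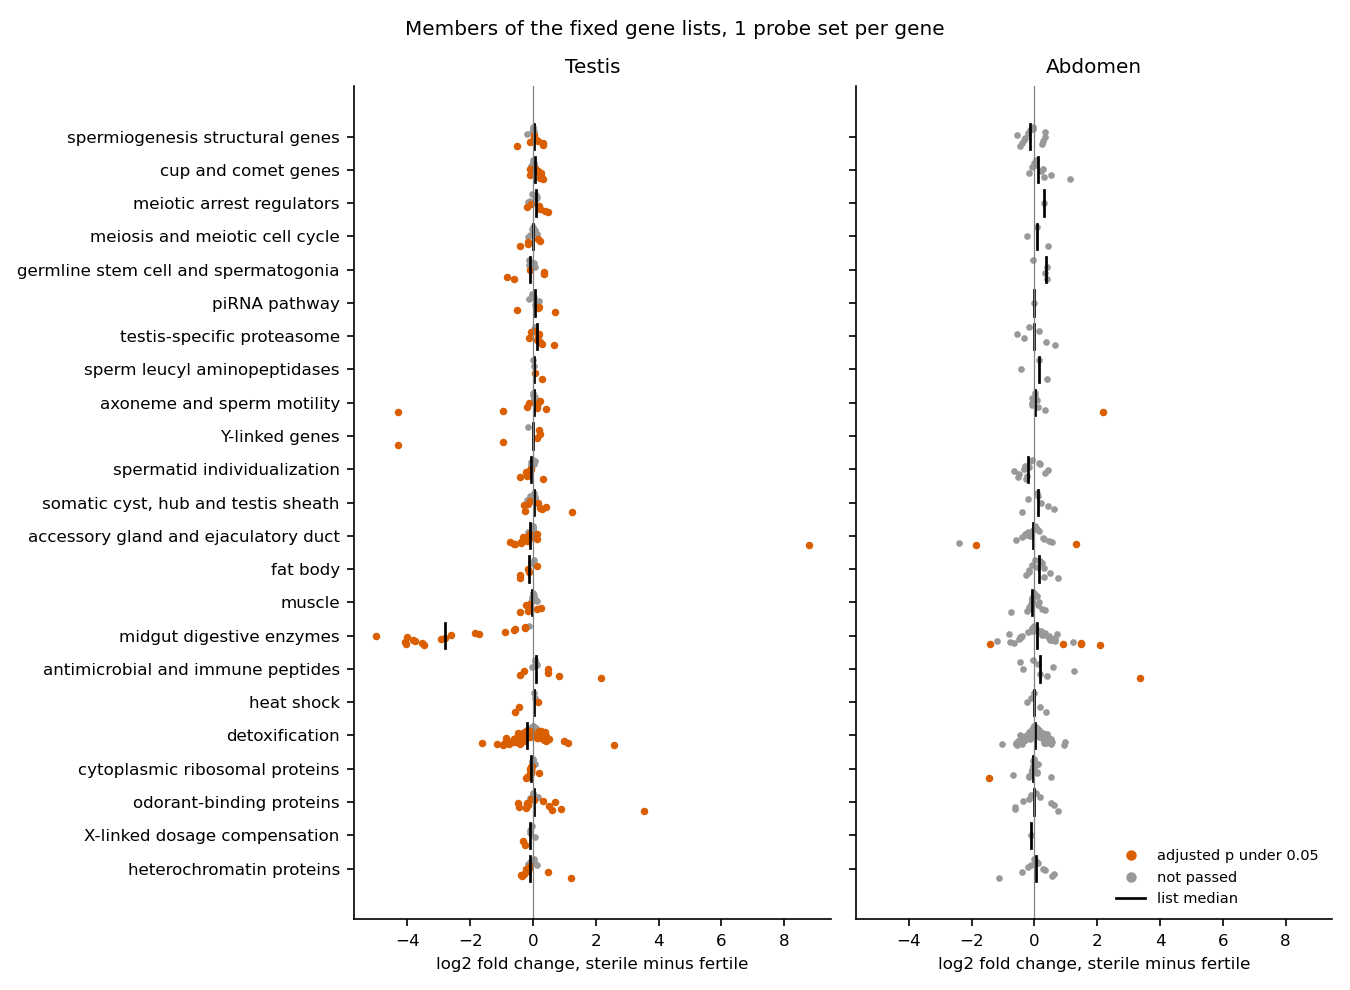
Log2 fold change, sterile minus fertile, of each tested member of the fixed gene lists (points, 1 probe set per gene) in testis (left) and abdomen (right), coloured by whether the gene passed an adjusted p of 0.05, with the list median as a black bar. In testis the midgut list has a median of -2.79, and in abdomen 0.07.

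The authors' deposited table marks 1233 probe sets as differing in testis, 870 higher in the fertile and 363 higher in the sterile line. Of these marked probe sets 1175 were tested here, and all 1175 passed in the same direction. This is no independent check, because the table describes the same testis comparison and 60.4% of all tested probe sets passed here. The marked probe sets also had an absolute fold score of at least 1.24. By the table's own p-values, 2034 probe sets lay under 0.05 after Benjamini-Hochberg adjustment.

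OdsH, the gene that differs between the lines, was called absent on all 6 testis arrays. Its probe set measured 127.6 ± 4.33 in sterile and 165.3 ± 25.1 in fertile testis (SD, n = 3; exact permutation p = 0.1, the smallest possible). In a limma fit of all probe sets the sterile values were lower (adjusted p = 0.0225), but not without sterile replicate C (adjusted p = 0.0645), fertile replicate A (0.105), fertile replicate C (0.0888) or the variance trend (0.0622), with a range of 0.00201 to 0.105 over all alternatives for OdsH. In abdomen its probe set measured 28.5 ± 18.1 in sterile and 34.4 ± 17.2 in fertile males (exact permutation p = 0.6, limma adjusted p = 0.969) and lay below the filter. No fold is given where both lines are at background. Whether either probe set lies in the exons that differ is not known here, so these values do not check the labels. The paralog of OdsH, unc-4, was also called absent on all testis arrays, at 69.1 ± 6.41 in sterile and 48.6 ± 7.58 in fertile testis (exact permutation p = 0.1).

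Transcripts that passed the test between sterile and fertile abdomens included genes of immunity, digestion and the accessory gland. Drs rose from 500.1 ± 91.9 to 5392 ± 1638 (SD, n = 3), a log2 fold change of 3.36 ± 0.25 (SE, adjusted p = 0.000681). CG3739 rose by 4.23 ± 0.34, tobi, an alpha-glucosidase gene under insulin control, by 4.12 ± 0.31 and CG13323 by 4.01 ± 0.39. Jon25Biii, a Jonah protease gene, rose from 1850 ± 116 to 7868 ± 930, and the lysozyme gene LysS from 2208 ± 113 to 6266 ± 639. Tektin-A, which encodes a protein of the axoneme, rose by 2.17 ± 0.36, CG31883 by 1.74, CG7916 by 1.57 and Jon44E by 1.49. The largest falls were those of CG6277, at -2.11 ± 0.18, and CG17197, at -1.97 ± 0.34. Mst57Da, an accessory gland transcript, fell by 1.86 ± 0.18. The other large falls had log2 fold changes of -1.54 (CG6271), -1.46 (Scsalpha2), -1.44 (RpL28, a ribosomal protein gene), -1.41 (LysX), -1.40 (CG18180) and -1.38 (CG9928). CG9297 fell by 1.92 in one probe set, while a brighter probe set of the same gene did not pass.

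In abdomen 38 of 6983 probe sets passed, 18 higher and 20 lower, and 567 had an unadjusted p under 0.05. With the replicate letter as a block 65 passed, 26 higher and 39 lower, and without a variance trend 15 passed, 8 higher and 7 lower. On simulated data this comparison recovered 8% of changes of 1 on the log2 scale, so most changes of that size were not detectable. The count was 23 without sterile replicate A, 22 without fertile replicate A and 21 without fertile replicate C. CG17197, CG31883, Tektin-A, Jon44E, CG18180, CG6271, Scsalpha2 and LysX lost their call with at least 1 array left out, and CG17197 also with the block.

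Of 41 midgut genes tested in abdomen 4 rose, Jon25Biii, LysS, Jon44E and Jon65Ai (by 0.92 ± 0.13, SE), and LysX fell (median 0.07, camera adjusted p = 0.134). No list of 16 tested passed limma's camera, with a preset or an estimated correlation, or fry, and the lowest unadjusted camera p was 0.0166. After quantile normalization the midgut list passed camera (median 0.17, adjusted p = 0.00787). The midgut list also passed without sterile replicate C, the immune list without fertile replicate B, and the muscle, immune and ribosomal protein lists without sterile replicate B. Immune genes counted 1 higher of 9, Drs (adjusted p = 0.134). Accessory gland genes counted 1 higher, Acp95EF (1.34 ± 0.19), and 1 lower, Mst57Da, of 19 (adjusted p = 0.804). Jon65Ai and Acp95EF also lost their call with at least 1 array left out. Tektin-A was the only call among 9 axoneme genes (adjusted p = 0.473) and RpL28 among 28 ribosomal protein genes (adjusted p = 0.473). None passed among 13 spermiogenesis (adjusted p = 0.625), 10 cup and comet (0.534), 6 testis proteasome (0.804), 14 individualization (0.473), 7 cyst and hub (0.804), 12 fat body (0.664), 19 muscle (0.625), 5 heat shock (0.804), 74 detoxification (0.804), 10 odorant-binding protein (0.928) and 11 heterochromatin genes (0.804). In the testis proteasome and heat shock lists the median was below and the mean above 0, with camera up. In the odorant-binding protein list the median was below and the mean above 0, and in the detoxification list the reverse held, both with camera down. Lists with fewer than 5 genes tested held meiotic arrest (1), meiosis (3), germline stem cell (4), piRNA (1), leucyl aminopeptidase (3) and dosage compensation genes (1), with none passing, and no Y-linked gene was tested. Adjusted over the list alone, midgut genes counted 6 higher and 3 lower, accessory gland genes 1 and 2, ribosomal proteins 1 and 1, odorant-binding proteins 1 and 1, fat body 1 and 0, and muscle 0 and 1. The 3' to 5' ratio of the eIF-4a control probe sets was -0.32 ± 0.01 on the log2 scale in sterile and 0.07 ± 0.25 in fertile abdomen (SD, n = 3; exact permutation p = 0.1, the smallest possible). That of actin was 1.68 ± 0.06 and 1.47 ± 0.33 (exact permutation p = 0.5), and that of GAPDH -1.18 ± 0.24 and -1.19 ± 0.09 (exact permutation p = 1).

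The difference between the sterile and fertile lines varied between testis and abdomen for 257 of 4774 genes tested in both. Of these, 74 had a higher and 183 a lower log2 fold change in testis. The counts were 93 and 145 after quantile normalization, 82 and 141 with arrays centred on their medians, and 53 and 132 with 1 array weight per tissue. On simulated data this test made more false calls than its threshold allows. Positive differences were found for Acp53C14b (adjusted p = 4.74e-10), with a log2 fold change of 0.55 in abdomen, and for Nazo, both called absent on all fertile testis arrays. Vps33B, a vacuolar sorting gene, had a difference of 2.43 ± 0.56 (SE), Gbp2 of 2.37 ± 0.23 and Phk-3 of 1.79 ± 0.37. Negative differences were found for CG8997, Eaat2, CG12057 and Mal-A1, a maltase gene of the midgut list, all called absent on the sterile testis arrays. The sizes of these 6 differences depend on the pseudocount, so neither a size nor an order is given. CG7916, with a difference of -4.49 ± 0.19, fell by 2.92 in testis and rose by 1.57 in abdomen. The count fell to between 127 and 140 with any 1 testis array left out, and was 408 without abdomen sterile replicate C and 387 without abdomen fertile replicate A.

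Of 17 genes called in both tissues, 10 changed in the same direction. Drs, CG31883, Acp95EF and Dip-B were higher in both, 4 genes where independent lists would share 2.51 (two-sided Fisher's exact test, p = 0.286). RpL28, Mst57Da, CG16926, CG6283, CG6295 and CG17197 were lower in both, 6 genes where 3.36 would be shared (Fisher's exact test, p = 0.076). Dip-B, CG16926, CG6283 and CG6295 were named after their values were seen. Across the 4774 genes the log2 fold changes of the tissues correlated at 0.122, and genes are not independent replicates.

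**Figure D3:**
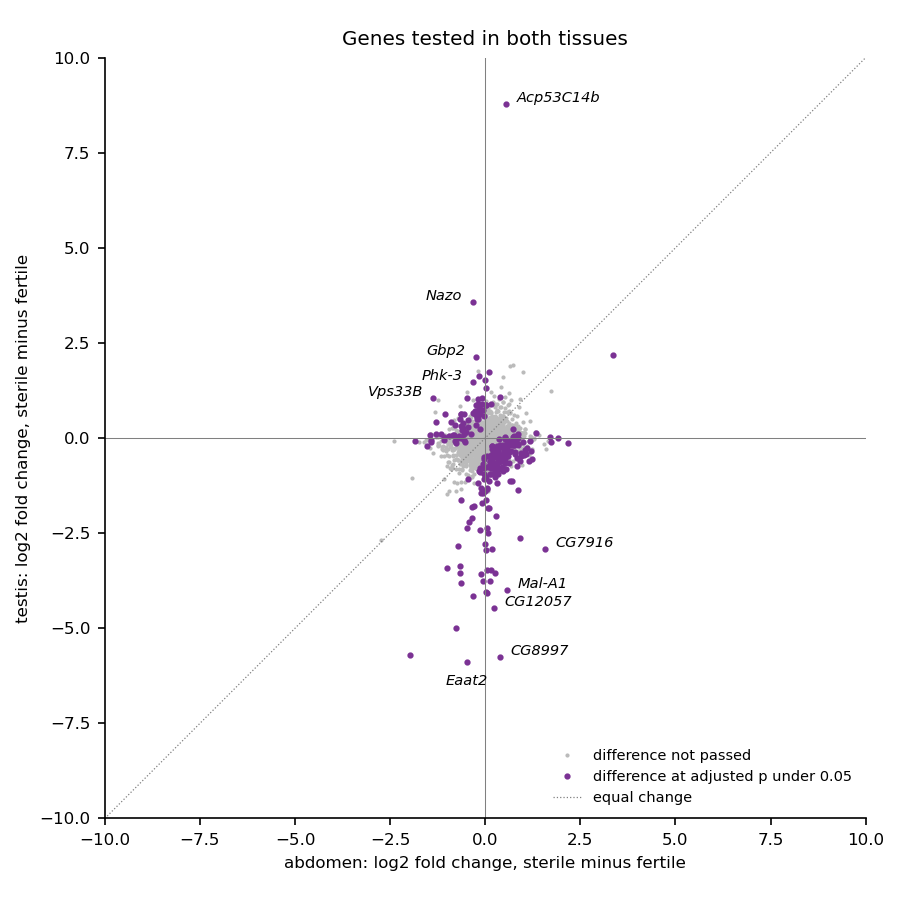
Log2 fold change, sterile minus fertile, in testis (vertical axis) against abdomen (horizontal axis) for 4774 genes tested in both tissues, with the 257 genes whose difference passed in purple and the 5 largest fitted differences in each direction named. The dotted line marks equal change. The heights of Acp53C14b, Nazo, CG8997, Eaat2, CG12057 and Mal-A1, absent in 1 testis line, depend on the pseudocount.

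Abdomens can include the testis, so the genes called in testis were followed in abdomen. The 1090 genes higher in sterile testis had a median log2 fold change of 0.06 in abdomen, against 0.01 for 2796 genes not called or not tested in testis (camera p = 0.0379, and p = 0.16 with an estimated correlation). The 2005 genes lower in sterile testis had a median of -0.03 (camera p = 0.0952, and p = 0.0353 with an estimated correlation). The p for genes higher in sterile testis was 0.279 without abdomen sterile replicate C, 0.102 without fertile replicate A and 0.107 without fertile replicate B, with a range of 0.00594 to 0.279 over all alternatives. For genes lower in sterile testis the median was -0.00363 without abdomen sterile replicate C. The limma camera p for these genes was then 0.176, and 0.381 without fertile replicate A, with a range of 0.0521 to 0.381 over all alternatives with the preset correlation.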

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

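The tests of gut expression in abdomen, of fat body and muscle genes and of the residual spread were chosen only after the results were seen. The difference between the lines varied between testis and abdomen for 257 genes by the interaction test in limma. Among them were 30 of the genes named by rule, 9 with a higher and 21 with a lower log2 fold change in testis. Acp53C14b and Nazo were called absent on all fertile testis arrays, and Jon65Ai, Jon25Bi, Mal-A1, CG17197, CG12057, Eaat2 and CG8997 on all sterile ones, so their 9 fitted differences depend on the pseudocount and give neither a size nor an order. The fitted differences above 0 were 8.24 for Acp53C14b, 3.90 for Nazo, 2.43 for Vps33B, 2.37 for Gbp2, 1.79 for Phk-3, 1.78 for Mst57Da, 1.55 for Scsalpha2, 1.39 for RpL28 and 0.80 for Obp56g. Mst57Da, Scsalpha2 and RpL28 owe theirs to falls in abdomen. Differences below 0 were found for genes of digestion, at -3.53 for Jon65Aiv, -3.54 for Jon65Ai, -3.79 for Bace, -4.06 for Jon65Aiii, -4.14 for yip7, -4.24 for Jon25Bi and -4.57 for Mal-A1. Further ones were -0.72 for apolpp, -0.85 for D1, -0.89 for FASN1, -0.96 for Hsp27, -1.08 for Cyp6a21, -1.18 for Drs, -1.203 for Acp95EF, -1.24 for Cyp6d5 and -2.31 for Tektin-A. The last were -3.73 for CG17197, -4.49 for CG7916, -4.71 for CG12057, -5.39 for Eaat2 and -6.13 for CG8997. Groups of 3 arrays were too small for a test of single outlying arrays.

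Midgut enzyme genes were lower in sterile testis. A difference in gut expression between the lines would lower them in abdomen too, which holds the gut, but there the same 19 genes had a median log2 fold change of 0.074, between -0.15 and 0.43 over 9 pairs of arrays, which argues against it. Gut tissue carried into the fertile testis samples may be a cause and stays open: a second gut list had a median of -0.19 over 9 tested genes, 5 lower and 1 higher, with an interval from -1.19 to 0.00. That median met the bound of -0.2 set beforehand for excluding gut tissue, but its interval spans the bound, and 7 of the 9 genes were detected on all sterile arrays, a baseline that could hide a small share, so after the value was seen the bound was not taken to exclude it. Fat body and muscle genes had a median of -0.0599 over 24 genes, all detected on the sterile arrays, which for the same reason leaves other abdominal tissue open. The bound for these genes had first been taken to exclude it, and this too was changed after the value was seen. A change within the testis was not tested.

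Of probe sets present on all arrays of 1 line and on none of the other, 23 differed by at least 3 on the log2 scale in testis, 7 higher and 16 lower in the sterile line. A sequence variant under the probes of 1 line may be the cause: of 12 other probe sets of these genes, all on the abdomen design, 8.33% differed by 1 or more in the same direction, that of CG17197 alone. By call, 3 of the 12 were lower in sterile abdomen as well, those of CG17197, CG6283 (-0.998) and CG6295 (-0.66), and none went the opposite way. Of all 6983 abdomen probe sets tested 0.54% were called, and 3 of 12 lies above that rate. The limma calls of CG17197 (adjusted p = 0.0451) and CG6295 (adjusted p = 0.0487) lay near the threshold, and that of CG17197 was lost with the replicate block. The rate was not matched to these genes, so little weight rests on it. A change confined to testis would also leave few of the other probe sets different by 1 or more, so a variant and a change of expression stay open. Carried-over gut tissue stays open for the falls as well. Of these, 3 are on the midgut list (Jon25Bi, Mal-A1 and epsilonTry), and the others were not tested for gut origin. epsilonTry was named after its values were seen.

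Testis gave 5995 calls and abdomen 38. The median residual SD of abdomen was 6.01 times that of testis, 0.30 against 0.05, and the spread of log2 fold changes beyond sampling variance was 2.29 times larger in testis, 0.44 against 0.19. That spread includes genes absent in 1 testis line, whose fitted changes depend on the pseudocount. Of 4774 genes tested in both tissues, 101 in testis and 92 in abdomen changed by at least 1 on the log2 scale. These counts include sampling noise, which was larger in abdomen. Both a smaller spread between the testis arrays and larger differences between the lines there are consistent with these values, and tissue, array design and signal method cannot be told apart.

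With 10 splits of 6 arrays no share under 0.05 can be reached. The real grouping gave 5995 testis calls and the highest other split 0, so 1 split gave as many. In abdomen the values were 38 and 1, again with 1 split as large, and 0 was the highest among other splits that part 3 letter pairs. For testis lists 8 of 10 splits passed as many as the real 1, the highest other passing 3. For abdomen lists 10 of 10 passed as many as the real 0, the highest other 4, or 2 among those parting 3 pairs. The abdomen shift of genes higher in sterile testis had a p as small in 3 of 10 splits (real 0.0379, smallest other 0.00298, or 0.149 among those parting 3 pairs). That of genes lower in sterile testis had 1 of 10 (real 0.0952, smallest other 0.15). For the difference between tissues 5 of 100 splits gave as many as 257, the highest 428, so chance is not excluded by this count. All 4 others with as many kept the real testis grouping, as did 10 of the 99 drawn (114 to 428 calls), and the highest without it was 14.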

How the results depend on the processing

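The fits with a minimum fold (limma treat), the count without midgut genes and the fit with 1 array weight per tissue were chosen only after the results were seen. The X against autosome test was not run, because no chromosome was assigned, and under the stricter filter OdsH has no value. Fold changes near the floor depend on the pseudocount, and signal over background limits what can be said of dim genes.

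The testis count of 5995 was 3152 with the stricter filter, where fewer probe sets were tested, 227 with an absolute log2 fold change of at least 1, 1490 with limma treat and 1233 in the authors' marks in their deposited table. It was 7524 with no filter, 5977 without midgut genes and 5396 to 5914 with 1 array left out. Of the 5995 calls, 5200 were shared with quantile normalization and 5186 with median centring. The testis lists that passed, 1, were 2 with no filter, 0 with the stricter filter, 3 with quantile normalization, 3 with median centring, 0 with an estimated correlation, 16 with fry and 1 to 2 with 1 array left out. The abdomen count of 38 was 65 with the replicate block, 15 without a variance trend, 70 at an adjusted p under 0.1, 24 with limma treat and 21 to 31 with 1 array left out. Abdomen lists, 0, were 1 with quantile normalization (midgut, up) and 0 to 3 with 1 array left out. The difference count of 257 was 96 with the stricter filter, 185 with tissue weights and 127 to 408 with 1 array left out. With equal groups the pooled spread averages both tissues, and leaving out an array shifts it toward the other tissue by construction. The adjusted p of OdsH in testis, 0.0225, was 0.0622 without a variance trend and 0.00201 to 0.105 with 1 array left out. In abdomen it was 0.93 to 1.00 with 1 array left out, and the direction turned without fertile replicate A (0.99). The abdomen shift of genes higher in sterile testis, a median of 0.0619, was 0.0291 with quantile normalization and 0.0437 to 0.093 with 1 array left out. Its camera p in limma was 0.116 with quantile normalization. The median of genes lower in sterile testis, -0.0267, lay between -0.0353 and -0.00363 with 1 array left out, and it passed camera with the preset correlation under no alternative. Except where a cause is named, the cause was not tested.

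In testis the letters did not pair the arrays, with same-letter correlations of -0.0683, 0.153 and 0.0541, and sterile A correlated best with fertile C (0.161). The replicate block gave 6117 testis calls and 2 testis lists, the proteasome list being added. In abdomen the block ended the call of CG17197 and changed no other call named. Of 101 genes named in testis, 4 lost their call in 5 of 1463 comparisons with alternatives (Lsd-2, Mst87F, S-Lap7 and spn-E). Of 22 in abdomen, 11 did so in 54 of 323, RpL28 only without a variance trend, and no named gene reversed.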

Other observations

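The gene families below, formed by symbols that share their leading letters, and the genes named here were all chosen only after the results were seen. Genes of the large subunit of the mitochondrial ribosome (mRpL) counted 15 higher and 4 lower of 42 in sterile testis, with a median log2 fold change of 0.08, and 24 higher and 4 lower after median centring. Those of the small subunit (mRpS) counted 5 higher and 8 lower of 23, with a median of -0.04, but 9 higher and 5 lower after quantile normalization and 6 of each after median centring, with medians of 0.03 and 0.01. RNA polymerase subunit genes (Polr) counted 10 higher and 2 lower of 18, with a median of 0.13. Translation initiation factor genes (eIF) counted 7 higher and 22 lower of 38, with a median of -0.11, and 9 higher and 18 lower after median centring. The CCT chaperonin genes counted 6 lower of 8 and none higher, with a median of -0.10, and 4 lower after median centring. The proton pump genes of the Vha family counted 4 higher and 9 lower of 18, with a median of -0.12. Except for mRpS, the signs of these medians were the same after quantile normalization and median centring. None of 39 families passed limma's camera in testis, the adjusted p being 0.149 for mRpL, 0.371 for Polr, 0.574 for eIF and CCT, 0.621 for Vha and 0.974 for mRpS.

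In abdomen the genes of mitochondrial complex I (ND) had a median log2 fold change of -0.14 over 31 genes, -0.10 after quantile normalization and -0.14 after median centring, with no single gene called. Among 23 families they passed limma's camera (adjusted p = 0.0013) but not with an estimated correlation (adjusted p = 0.988).

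Of the 7 genes called in both tissues with opposite directions, Gdh, which encodes glutamate dehydrogenase, had log2 fold changes of -0.37 ± 0.02 (SE) in testis and 0.79 ± 0.13 in abdomen. Mpcp2, a mitochondrial phosphate carrier gene, had -0.07 ± 0.02 and 1.18 ± 0.13, and CG11594 had -0.60 ± 0.04 and 1.15 ± 0.20. Scsalpha2 went the other way, with 0.09 ± 0.02 in testis and -1.46 ± 0.21 in abdomen. Tektin-A, Jon65Ai and CG7916 were the other 3, each lower in sterile testis and higher in sterile abdomen.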
